A study of Danio rerio with 11 samples.

How the data were processed

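RNA of whole zebrafish embryos was measured on 11 dual-colour oligonucleotide arrays on 4 slides. Per the labels' protocols, each replicate held 50 fertilized eggs exposed for 48 h at 28.5 °C to a poly(amidoamine) (PAMAM) dendrimer or to embryo water, and 200 ng of total RNA was labelled per channel. On the 3 arrays of generation 3 (G3) and the 3 arrays of generation 4 (G4), RNA of exposed embryos was in Cy5 and a pool of the water controls of the same dendrimer was in Cy3, with no dye swap. On 4 of the self-to-self arrays, pooled control RNA was in both channels. The G3 pool was used on self-to-self arrays 1 and 3, and the G4 pool on arrays 2 and 5 per the labels. Self-to-self array 4 set the G3 pool in Cy5 against a pool of 0.1% DMSO controls in Cy3. The labels of array 5 conflict, with 3 dpf (days post fertilization) for Cy5, 2 dpf for Cy3 and 2 dpf in its description. The labels also conflict on the dose. The treated samples give 1.5 mg/L for both dendrimers, and the protocol attached to the self-to-self samples gives 0.05 µM for G3 and 0.5 µM for G4.

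Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 10.5.1.1, which gave for each spot a median intensity of the spot and of its local background in each channel. Per the file headers, the same software also gave background-subtracted and dye-normalized processed intensity values, and a log10 ratio of Cy5 over Cy3 with its p-value. The deposited value table holds a log ratio per spot near the log2 scale, whose normalization the authors do not state. Over all spots that were not controls, its values correlated with the log2 ratios computed here at r between 0.9985 and 1, in the direction Cy5 over Cy3. The slopes lay between 1.005 and 1.05 and the medians of the deposited values between 0.00102 and 0.0115. A column of mean signals is not used here, because the deposited files of intensity per spot hold median signals.

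Ratios were computed from the median signals with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for blocked fits. Background was corrected by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess. Control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. Each array held 45220 spots, of which 43803 were not controls and covered 43603 probes. A probe was tested when it was well above background in Cy3 or Cy5 on at least 3 of the 9 arrays used, which left 35745 probes. Probes were named through their RefSeq accessions, which 26981 probes carried, against a RefSeq gene table of the assembly GRCz12tu, used only for names. The file headers give danRer6 as the build of the probe design, and no coordinates are given here. This named 25069 probes of 12858 genes and left 18534 probes unnamed, and 11769 named genes had a tested probe. A gene was represented by its tested probe of highest mean intensity, and other probes of a named gene that pointed the opposite way are stated.

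The control arm had 2 units: the mean of self-to-self arrays 1 and 3, which share their pool, and array 2, by its label from the G4 pool. If array 2 held the G3 pool, the arm would have 1 unit, and the SE and p-values against it would leave out the spread between pools. Treated arrays were compared with the control arm, meant to subtract a dye effect of each probe common to the arrays, and G3 with G4 directly. Across probes, the ratios of the treated arrays correlated with self-to-self array 1 at −0.183 (G3 array 2) to 0.7 (G3 array 1). The subtracted pattern was therefore not shared by all arrays. The 3 comparisons came from 1 fit (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. All p-values are two-sided and adjusted p-values of genes are from limma. A p-value rests on the spread between the arrays of replicate vessels within each dendrimer, each with its own 50 embryos, and between the 2 control units of pooled RNA, which are no replicate vessels. That spread enters the comparison of G3 with G4 too, and the number of arrays limits the precision. By the labels, the 3 arrays of a dendrimer share their Cy3 pool, so the spread between them leaves out that between pools. A difference of G3 from G4 in the ratios cannot be told apart from a difference of their pools by these p-values. The replicate numbers and slides were checked as blocks and are given in the closing section. Array 4 was left out because its Cy3 pool was not a water control, and array 5 because of its stage labels.

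Before the data were examined, 29 gene lists were fixed: acute phase and inflammation, complement and coagulation, neutrophil and macrophage markers, oxidative stress and glutathione, heat shock and unfolded protein response, xenobiotic metabolism, DNA repair and apoptosis, cell cycle and DNA replication, cholesterol synthesis, lipid and apolipoprotein metabolism, liver and yolk secreted proteins, exocrine pancreas and intestine, hatching gland, skeletal muscle, heart, erythrocytes and heme, endothelium, eye with lens and phototransduction, melanophores and pigment, nervous system, skin and keratins, ionocytes, lysosome and endocytosis, hypoxia and glycolysis, circadian clock, extracellular matrix and cartilage, early embryo and segmentation, oxidative phosphorylation, and ribosomal proteins. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were run beside it. Camera and fry left out members with a missing value, so a few lists were tested with fewer members than were counted. Members were also adjusted over the list alone.

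Named genes followed a rule fixed at the same time. It took, among genes that passed with all treated arrays on the same side of self-to-self arrays 1 to 3 (or all G3 arrays on the same side of all G4 arrays), the 12 with the largest change on each side. Genes named only as a clone or a locus were excluded. Of all 11769 named genes, 16.8% lay so apart in G3, 43.4% in G4 and 25.7% between G3 and G4. Arrays on the same side are therefore no added support for a gene named by this rule. A few genes that the rule takes are not reported here. For each list described, up to 4 passing members with the largest change were added, or the 2 members with the smallest p where none passed. Which lists to describe was chosen after the values were seen, Cy5 values included. Other genes named are said to be chosen after their values were seen.

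The levels in Cy5 alone and in Cy3 alone were taken from the loess-normalized arrays after Aquantile scaling of the mean log2 intensities between arrays, and compared with the same channel of the control arm. The correlation of the G3 and G4 changes was set beside 100 simulations without any effect that shared the control arm. The fit and the list test were tested on simulated data for 35745 probes with 100 probes changed at each size. A log2 change of 1 was recovered for 73% of changed probes in the G3 design, 76% in the G4 design and 85% in the direct comparison of G3 with G4. A log2 change of 2 was recovered for 100%, 99% and 100%. The simulated noise had the moderated spread of each probe, and the planted changes loosened the adjustment over probes. These shares are therefore not the power of the real comparisons. In the real G3 comparison, mmp9 at 3.31 (adjusted p = 0.356, limma) and irg1l at 2.74 (adjusted p = 0.296, limma) did not pass. There were 13, 11 and 8 false calls, and the shifted list was called with 0 others (camera; fry was not run in this test). The value 0 counts list calls on simulated data. The simulated probes varied independently, while the correlation estimated within the real lists reached 0.607. The 0 therefore does not bear on false list calls among correlated genes.

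Alternatives fixed before the values were seen were no background correction, the scanner's own log ratios, median centring in place of loess, scaling between arrays, the deposited values, no filter or a stricter filter of dim probes (24237 probes), treated ratios tested against 0, self-to-self arrays unaveraged, arrays 4 and 5 added, only the groups compared in the fit, a trended robust prior, array weights, replicate and slide blocks, each array left out in turn, an added fold threshold, the mean of a gene's probes, the other list tests and separate controls. Alternatives added after the data were seen were array 5 alone as the control arm, arrays 1 and 2 averaged, arrays 1 to 3 as 1 unit, the Cy5 channel alone, and doubted arrays left out. The 345 tested probes with a missing value on an array were fitted on the arrays left. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.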

Results

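Transcript levels were measured in whole zebrafish embryos exposed to poly(amidoamine) (PAMAM) dendrimers, branched polymers that carry amine groups on their surface. Generation 4 (G4) has an additional shell of branches over generation 3 (G3). Each dendrimer had 3 arrays, with exposed embryos in Cy5 and a pool of that dendrimer's water controls in Cy3. The control arm came from 3 self-to-self arrays with pooled control RNA in both channels, counted as 2 units by the labels of their pools. A further pair of self-to-self arrays was not used in the comparisons. The treated samples are labelled 1.5 mg/L and 48 h for both dendrimers, while the protocol of the control samples gives 0.05 µM for G3 and 0.5 µM for G4, so equal doses are taken from the labels only. Between 61.5% (G4 array 3) and 83.5% (G3 array 1) of probes were well above background in at least 1 channel, with 0 saturated spots per the scanner. Median Cy5 signals ran from 136.5 to 263.5 over backgrounds of 50 to 56, and median Cy3 signals from 73 to 148 over backgrounds of 26 to 38. The number of arrays limits the precision of every value.

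The comparison of G3 with the control arm asked which transcripts differed after exposure to the smaller dendrimer. s100t, a member of the S100 family of calcium-binding proteins, fell by 1.63 on the log2 scale (SE 0.126, 3 G3 arrays against 2 control units; adjusted p = 0.0162, limma). This was a 3.1-fold lower level, seen in 3 of 3 arrays. Inflammation genes were higher as a group, with a median log2 change of 0.53 over 36 measured members. Cell cycle genes were higher by a median of 0.28, and genes of the lens and photoreceptors were lower by a median of −0.26. For each of these 3 lists camera gave an adjusted p = 0.647 with an estimated correlation, and no member passed over all probes. s100t was the only probe called in this comparison. An unadjusted p under 0.05 was reached by 1950 of 35745 probes, against 1787 by chance, so list members are counted below adjusted over the list alone.

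Among the acute phase and inflammation genes, 33 of 36 had a change above 0 in G3 (adjusted p = 9.16e-17, camera; adjusted p = 0.647 with an estimated correlation). The count adjusted over the list alone was 13 higher and 1 lower. These included tnfb, a tumor necrosis factor (log2 change 2.32, SE 0.337), and ptgs2b, an inducible prostaglandin synthase (1.35, SE 0.215). They also included irg1l, an immune-responsive gene (2.74, SE 0.487), and mmp9, a matrix-degrading protease (3.31, SE 0.616). Adjusted over all probes, none of these 4 passed, with adjusted p from 0.167 for tnfb to 0.356 for mmp9, although 3 of 3 arrays were higher for all 4. The list's median ratio lay between 0.40 and 0.68 on the G3 arrays and between −0.07 and 0.06 on self-to-self arrays 1 to 3. The list's change was 0.47 in Cy5 alone, and in the Cy3 pool −0.02. Within slides 1, 2 and 3 the difference of G3 from the self-to-self array was 0.34, 0.73 and 0.56. Neutrophil and macrophage markers had a median of 0.26 over 21 genes (adjusted p = 0.000768, camera; adjusted p = 0.721 with an estimated correlation). A single marker was higher adjusted over the list alone, namely mmp9. lgals9l1, a galectin at 0.53 (SE 0.15), was not among these markers higher, though it was among the 13 inflammation genes. The lists share mmp9, lgals9l1 and ncf1. The markers' median was 0.13 in Cy5 alone.

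Cell cycle and DNA replication genes had changes above 0 for 76 of 80 members in G3 (adjusted p = 6.82e-21, camera; adjusted p = 0.647 with an estimated correlation). The smallest p values were those of pcna, the sliding clamp of DNA replication (log2 change 0.59, SE 0.142), and rrm1, a ribonucleotide reductase subunit (0.53, SE 0.131). Neither passed over all probes, and adjusted over the list alone no member did. Within slides 1 to 3 the list's difference was 0.41, 0.27 and 0.23. On self-to-self array 4, with the G3 pool in Cy5 against the DMSO pool, the same list had a median ratio of −0.59. Its Cy3 level, centred per gene, was −0.18 to −0.07 on the G3 arrays. That level was 0.01 to 0.07 on the G4 arrays and 0.32 in the DMSO pool. The G3 pool was thus the lowest for this list, and a low pool cannot be told apart from a response to G3. In the DNA repair and apoptosis list the median was 0.14 over 62 genes (adjusted p = 0.000768, camera; adjusted p = 0.682 with an estimated correlation). Its smallest p values were those of plk3 (0.41, SE 0.124) and chek1, a checkpoint kinase (0.42, SE 0.148), which did not pass.

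Of 62 genes of the eye, lens and phototransduction list, 8 had changes above 0 in G3 (adjusted p = 4.8e-12, camera; adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone, 4 were lower. They included sagb, an arrestin of photoreceptors (log2 change −0.61, SE 0.127), and opn1mw1, a cone opsin (−0.73, SE 0.158). Within slides 1 to 3 the list's difference was −0.37, −0.205 and −0.19. Nervous system genes had a median of −0.12 over 71 genes (adjusted p = 0.00109, camera; adjusted p = 0.682 with an estimated correlation). The smallest p values were those of the calretinin genes calb2a (−0.54, SE 0.163) and calb2b (−0.49, SE 0.162), which did not pass. Ribosomal protein genes had a median of −0.12 over 78 genes (adjusted p = 0.00109, camera; adjusted p = 0.682 with an estimated correlation), with rpl24 at −0.59 (SE 0.156), which did not pass. Their direction was not kept when G3 ratios were tested against 0, where the list's median was 0.17 and rpl24 stood at 0.21. The oxidative stress list had a median of 0.12 over 44 genes (adjusted p = 0.00285, camera; adjusted p = 0.721 with an estimated correlation). prdx1, a peroxiredoxin, was at 0.43 (SE 0.163) and msrb3, a methionine sulfoxide reductase, at −0.35 (SE 0.134), with 1 of 2 other msrb3 probes opposing. The other 21 lists had medians between −0.07 and 0.10 in G3 and adjusted p from 0.192 to 0.954.

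Without any 1 of G3 arrays 1, 2 and 3, G4 array 3 or self-to-self array 2, the adjusted p of s100t lay between 0.0518 and 0.755, and over all alternatives between 0.00128 and 1. The count was 53 without G4 array 1 and 15 in Cy5 alone, 5 lists in place of 8 were called without G3 array 1, and fry called 0 lists one way and 0 in either direction; with self-to-self arrays 1 to 3 as 1 unit, s100t was not called. The neutrophil and oxidative stress lists (adjusted p = 0.0554 each, camera), the ribosomal list (0.0824) and the nervous system list (0.0987) each lost their call in 1 fit without 1 array. The ribosomal call was also lost in Cy5 alone (adjusted p = 0.259, camera).

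The comparison of G4 with the control arm asked the same of the larger dendrimer. Of 35745 probes, 664 rose and 184 fell, among them 277 named genes that rose and 67 that fell (limma). The skeletal muscle list was higher by a median of 0.94 on the log2 scale, and the oxidative phosphorylation list by 0.45 (adjusted p = 0.293 and adjusted p = 0.372 with an estimated correlation). irg1l rose 9.08-fold (log2 change 3.18, SE 0.487, 3 G4 arrays against 2 control units, adjusted p = 0.0224). mmp9 rose 7.54-fold (SE 0.616 on the log2 scale, adjusted p = 0.0489). In Cy5 alone irg1l stood at 2.18 (adjusted p = 0.1) and mmp9 at 1.96 (adjusted p = 0.202), no longer called. The glutamate receptor genes gria1a and gria2b fell, and s100t fell by 0.98 (SE 0.126, adjusted p = 0.018; −1.23 in Cy5 alone) in 3 of 3 arrays.

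The Cy3 pool of the G4 arrays differed from the other control RNA in many of the same genes. Self-to-self array 2, labelled with the G4 pool, had Cy3 values that correlated across probes at 0.949 to 0.956 with the Cy3 of the G4 arrays and at 0.979 to 0.99 with that of the G3 arrays. The Cy5 of arrays 1 to 3 correlated at 0.969 to 0.995 with the Cy3 of the G3 arrays. With the Cy3 of the G4 arrays it correlated at 0.948 to 0.963. Cy5 alone thus sets G4 against control RNA unlike the G4 pool, and cannot separate exposure from a difference of pools. For the 277 genes that rose, the median change was 0.92 in the ratios, 0.15 in Cy5 alone and −0.78 in Cy3 alone. In Cy5, 195 of these genes had the same sign as in the ratios, 81 the opposite sign and 1 had a missing value. For the 67 that fell, the medians were −0.71 in the ratios, −0.22 in Cy5 and 0.51 in Cy3, and 17 had the opposite sign in Cy5. Of the 38 genes reported for G4 by the naming rule, s100t alone kept its call in Cy5 (adjusted p = 0.0415), 28 lost it and 9 turned direction. ptgs2b and stard14, described below and also called in G4, are not among the 38. They stood at 1.89 and 1.38 in Cy5 alone.

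Of 60 skeletal muscle genes, 28 rose in G4 and 32 did not pass (adjusted p = 4.73e-22, camera; adjusted p = 0.293 with an estimated correlation; adjusted p = 0.00512, fry). The count adjusted over the list alone was 49 higher and 1 lower. The fast troponin gene tnni2a.4 rose by 2.40 (SE 0.397), the slow myosin gene smyhc2 by 2.20 (SE 0.329), the actin gene actc1a by 2.03 (SE 0.326) and the parvalbumin gene pvalb4 4.29-fold (SE 0.28 on the log2 scale). Of 3 other probes of smyhc2, 1 pointed the opposite way. In Cy5 alone the list's change was 0.06, and in the Cy3 pool −0.91. In Cy5 alone tnni2a.4 stood at −0.29 and pvalb4 at −0.53, the opposite direction. Within slides 2 and 3 the list's ratio differed from the self-to-self array by 0.97 and 0.74.

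Of 79 oxidative phosphorylation genes, 14 rose in G4 (adjusted p = 4.13e-11, camera; adjusted p = 0.372 with an estimated correlation). Members higher when adjusted over the list alone numbered 39. ucp2, a mitochondrial carrier, rose by 1.78 (SE 0.291), ndufs7, a complex I subunit, by 1.204 (SE 0.202), the citric acid cycle gene suclg1 by 0.99 (SE 0.182) and the adenine nucleotide carrier slc25a4 by 0.98 (SE 0.19). The list's change was −0.02 in Cy5 alone, the opposite direction, and in the Cy3 pool −0.44. Within slides 2 and 3 the list's difference was 0.51 and 0.29.

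Of 48 heat shock and unfolded protein response genes, 5 rose in G4 (adjusted p = 0.00449, camera; adjusted p = 0.348 with an estimated correlation; adjusted p = 0.0103, fry). Adjusted over the list alone, 11 were higher and 1 was lower. hsp90aa1.1, a cytosolic chaperone, rose 4.33-fold (SE 0.171 on the log2 scale, adjusted p = 0.0118, higher in 3 of 3 arrays), hsc70 by 1.48 (SE 0.253), the collagen chaperone serpinh1b by 1.16 (SE 0.229) and hspa4a by 0.78 (SE 0.159). In Cy5 alone the list's change was 0.15, and in the Cy3 pool −0.13. hsp90aa1.1 stood at 0.955 in Cy5 alone (adjusted p = 0.0588), hsc70 at 1.08 (adjusted p = 0.104), hspa4a at 0.68 (adjusted p = 0.104) and serpinh1b at 0.40 (adjusted p = 0.601), none of them called.

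Of 36 acute phase and inflammation genes, 5 rose in G4 (adjusted p = 6.45e-06, camera; adjusted p = 0.598 with an estimated correlation). The count adjusted over the list alone was 13 higher. Besides irg1l and mmp9, the transcription factor genes cebpb (log2 change 2.26, SE 0.339, adjusted p = 0.021) and fosab (1.99, SE 0.272, adjusted p = 0.018) rose in 3 of 3 arrays. ptgs2b rose by 1.34 (SE 0.215, adjusted p = 0.0254). tnfb, at 1.195 (SE 0.337, adjusted p = 0.0867), did not pass. The list's change was 0.22 in Cy5 alone, and in the Cy3 pool −0.32. The list's median ratio was 0.885 on G4 array 1, which had the widest ratios of the treated arrays, 0.17 on array 2 and 0.305 on array 3. Of 21 neutrophil and macrophage markers, 1 rose, and the median was 0.49 in the ratios and −0.03 in Cy5 alone, the opposite direction (adjusted p = 0.000635, camera; adjusted p = 0.598 with an estimated correlation). Members higher when adjusted over the list alone numbered 7.

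Of 71 nervous system genes, 2 fell in G4, and the median was −0.30 (adjusted p = 2.84e-09, camera; adjusted p = 0.293 with an estimated correlation; adjusted p = 0.0219, fry). Adjusted over the list alone, 22 were lower. The AMPA receptor gene gria2b fell by 0.79 (SE 0.164) and slc32a1, which loads GABA into synaptic vesicles, by 0.64 (SE 0.133). Outside the list, gria1a, another AMPA receptor gene, fell by 1.16 (SE 0.239), foxp2, a transcription factor of neurons, by 1.03 (SE 0.138), and npvf, which encodes a neuropeptide, by 0.95 (SE 0.145). In Cy5 alone the list's change was −0.07, and in the Cy3 pool 0.28. gria1a stood at −0.12 in Cy5 alone and 1.04 in the Cy3 pool, and gria2b at −0.22 and 0.57. The other named genes that fell, pcdh2ac, ralgps2, nbeaa, septin5b, nfia, fam168b, dab1a and tnika, lay between −1.08 and −0.89. In Cy5 alone pcdh2ac stood at 0.01, ralgps2 at 0.07, nfia at 0.42 and fam168b at 0.06, the opposite direction.

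The remaining named genes that rose in G4 were ckba, a creatine kinase (log2 change 2.52, SE 0.424), the fin fold gene and2 (2.43, SE 0.43), jac7 (2.41, SE 0.492), the cochaperone gene fkbp5 (2.27, SE 0.434) and tmem38a, an ion channel of the sarcoplasmic reticulum (2.19, SE 0.328). In Cy5 alone ckba stood at −0.29, and2 at −0.28 and jac7 at −0.02, the opposite direction, and tmem38a at 0.10 (adjusted p = 0.892) and fkbp5 at 1.34 (adjusted p = 0.124), no longer called. Of 16 melanophore and pigment genes, 2 rose, namely the pteridine synthesis genes pts (1.12, SE 0.21; 1 of 1 other probe opposing) and gch2 (0.90, SE 0.166). Their list had a median of 0.44 (adjusted p = 0.00184, camera; adjusted p = 0.293 with an estimated correlation; adjusted p = 0.0016, fry). In Cy5 alone it stood at 0.03 (adjusted p = 0.905, camera), no longer called. The count adjusted over the list alone was 8 higher. Of 62 DNA repair and apoptosis genes, 2 rose, among them endog, a mitochondrial nuclease (0.80, SE 0.164). That list had a median of 0.23 (adjusted p = 0.00396, camera; adjusted p = 0.598 with an estimated correlation). In Cy5 alone it stood at 0.135 (adjusted p = 0.227, camera), no longer called. Members higher when adjusted over the list alone numbered 14, with 1 lower.

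The other lists called in G4 each had an adjusted p between 0.372 and 0.648 with an estimated correlation. The medians of those higher were 0.60 for skin and keratins (2 of 32 rose, adjusted p = 0.000639), 0.40 for oxidative stress (2 of 44, adjusted p = 1.41e-05), 0.25 for the cell cycle (1 of 80, adjusted p = 0.000591) and 0.32 for extracellular matrix (5 of 52, adjusted p = 0.00451). Erythrocytes followed with 0.28 (1 of 38, adjusted p = 0.00267). The medians were 0.39 for xenobiotic metabolism (adjusted p = 0.00257), 0.40 for the heart (adjusted p = 0.00396) and 0.25 for lipid metabolism (adjusted p = 0.0373, with 1 of 63 that fell). Without 1 array the lipid call was lost in 2 fits (adjusted p = 0.0629 to 0.0888, camera). Ribosomal protein genes were lower, with a median of −0.14 (adjusted p = 3.97e-05), but stood at 0.13 when G4 ratios were tested against 0. Adjusted over the list alone, 12 skin, 11 oxidative stress, 1 cell cycle, 16 matrix, 3 erythrocyte, 9 xenobiotic, 2 heart and 8 lipid genes were higher. Lower ones numbered 1 for oxidative stress, xenobiotic metabolism and erythrocytes and 3 for matrix and lipid metabolism. In Cy5 alone the skin list stood at −0.17, the heart at −0.17, extracellular matrix at −0.06, xenobiotic metabolism at −0.04, lipid metabolism at −0.02 and ribosomal proteins at 0.02, the opposite direction, while the cell cycle stood at 0.38. Oxidative stress stood at 0.08 (adjusted p = 0.73) and erythrocytes at 0.04 (adjusted p = 0.762), no longer called. These values depend on the control RNA. The cell cycle level in Cy5, centred per gene, was 0.08 to 0.25 on the G4 arrays and −0.24 to −0.17 on self-to-self arrays 1 to 3. On array 5, labelled with the G4 pool, it was 0.04. The skin level in Cy5 was 0.525, −0.23 and −0.20 on G4 arrays 1, 2 and 3 and −0.41 on array 5. Median ratios on G4 arrays 1, 2 and 3 were 1.02, 0.21 and 0.445 for skin, 0.915, 0.18 and 0.30 for the heart and 0.69, 0.14 and 0.22 for xenobiotic metabolism. The 12 lists not called were liver (median 0.36, adjusted p = 0.0517), complement (0.44, 0.0623), ionocytes (0.27, 0.0736), hatching gland (0.65, 0.149), hypoxia (0.16, 0.149), cholesterol synthesis (0.20, 0.179), exocrine pancreas (0.125, 0.798), lysosome (0.05, 0.798), early embryo (0.04, 0.798), circadian clock (0.02, 0.554), endothelium (−0.04, 0.554) and the eye (0.06, 0.882). Among their members, 4 of 47 hypoxia genes rose, as did 2 of the eye, 2 of ionocytes, 1 of the hatching gland and 1 of cholesterol synthesis, and 1 of the circadian clock fell. Adjusted over the list alone, 13 hypoxia genes were higher and 4 lower. The eye list, called in G3, stood in Cy5 alone at −0.25 in G3 and −0.27 in G4, with −0.39 in the Cy3 pool of the G4 arrays. Tested in either direction, fry called 15 of the 29 lists in G4, among them hypoxia (adjusted p = 0.00357), the eye (adjusted p = 0.00833), cholesterol synthesis (adjusted p = 0.039) and circadian clock (adjusted p = 0.0429).

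The G4 count of 848 was 1819 without G3 array 2, 152 without G3 array 3, 512 without G4 array 1, 1888 without G4 array 2, 1 without G4 array 3, 331 without self-to-self array 1, 2545 without array 3, and 0 without array 2, where 3631 probes had an unadjusted p under 0.05 (limma); it was also 0 with arrays 1 to 3 as 1 unit (3744). In Cy5 alone it was 28, with median centring in place of loess 1446 (1422 higher and 24 lower), and with slides as blocks 292, where 23 of 38 named genes were no longer called.

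**Figure D1:**
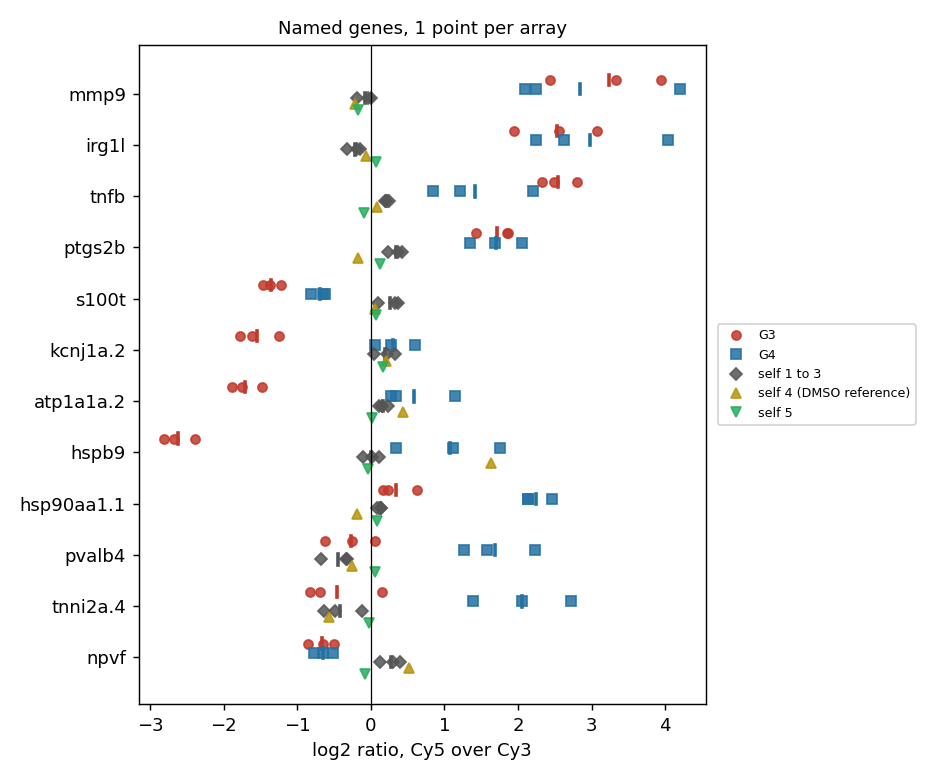
Each point is the log2 ratio of Cy5 over Cy3 of a named gene on 1 array, for the G3, G4 and self-to-self arrays, and vertical ticks mark the mean of 3 arrays. hspb9, atp1a1a.2 and kcnj1a.2 lie below 0 on all 3 G3 arrays and above 0 on all 3 G4 arrays, while mmp9, irg1l and ptgs2b lie above 0 on all 6.

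The direct comparison of G3 with G4 asked where molecules that differ by a shell of branches differed in response, at doses labelled equal. hspb9, which encodes a small heat shock protein, was 13-fold lower in G3 (log2 difference −3.70, SE 0.302, 3 arrays each, adjusted p = 0.00561, limma). The sodium pump gene atp1a1a.2 was 4.9-fold lower (−2.29, SE 0.224, adjusted p = 0.00561) and the potassium channel gene kcnj1a.2 was lower by −1.85 (SE 0.18, adjusted p = 0.00561). In each case all 3 G3 arrays lay below all 3 G4 arrays, which the naming rule required. Against the control arm, the values in G3 were −2.63 for hspb9, −1.87 for atp1a1a.2 and −1.77 for kcnj1a.2, with adjusted p of 0.134, 0.149 and 0.0919, which did not pass. In G4 they were 1.07, 0.43 and 0.08, with adjusted p of 0.11, 0.332 and 0.845, which did not pass either. In the G4 arrays' Cy5 alone these genes stood at −1.22, −1.28 and −1.26 against the control arm, below 0 as in G3, and in their Cy3 pool at −2.29, −1.70 and −1.34. Of 35745 probes, 145 were higher and 684 lower in G3 than in G4, among them 43 and 318 named genes. The arrays of each dendrimer share their Cy3 pool, so these calls do not separate the dendrimers from their pools.

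The difference of G3 from G4 in Cy5 alone was −1.31 for hspb9, −0.525 for atp1a1a.2 and −0.465 for kcnj1a.2, with adjusted p between 0.171 and 0.484. For the 318 genes lower in G3, the median difference was −0.89 in the ratios, −0.06 in Cy5 alone and 0.81 in Cy3 alone, and 139 had the opposite sign in Cy5. For the 43 genes higher, the medians were 0.65, −0.09 and −0.72, and 27 had the opposite sign in Cy5. Without G3 array 2, which had the narrowest ratios of the treated arrays, and G4 array 1, which had the widest, 1377 probes were called.

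Of 60 skeletal muscle genes, 32 were lower in G3 than in G4 and 28 did not pass (median −0.94, adjusted p = 4.62e-27, camera; adjusted p = 0.203 with an estimated correlation). The count adjusted over the list alone was 53 lower and 2 higher. tnni2a.4 differed by −2.51 (SE 0.355), pvalb4 by −1.96 (SE 0.251), actc1a by −1.82 (SE 0.292) and tnnt3a by −1.65 (SE 0.218). The list's medians against the control arm were 0.02 in G3 and 0.94 in G4, and its Cy3 level was higher by 0.86 on the G3 arrays. In Cy5 alone its difference was −0.01. Within slides 2 and 3 the list's difference in the ratios was −0.90 and −0.81. These 4 genes stood between 0.05 and 0.66 in Cy5 alone, the opposite direction. Of 79 oxidative phosphorylation genes, 8 were lower (median −0.43, adjusted p = 3.98e-13, camera; adjusted p = 0.36 with an estimated correlation). Members lower when adjusted over the list alone numbered 46. They included ndufa7 (−0.88, SE 0.115), ndufs7 (−0.85), slc25a4 (−0.82) and uqcrc1 (−0.59). Their list stood at 0.09 in Cy5 alone, the opposite direction.

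Of 62 eye and lens genes, 9 were lower in G3 (median −0.30, adjusted p = 6.44e-06, camera; adjusted p = 0.555 with an estimated correlation). Adjusted over the list alone, 18 were lower and 1 higher. They included the crystallin genes crygm2d13 (−1.37, SE 0.216), crygmx (−0.96) and cryaa (−0.92, SE 0.13) and the lens filament gene bfsp2 (−0.95). The list stood at 0.07 in Cy5 alone and these 4 genes between 0.001 and 0.34, the opposite direction. Of 48 heat shock genes, 4 were lower, namely hspb9, hsp90aa1.1 (−1.90, SE 0.153), dnajb1b (−1.48, SE 0.312) and serpinh1b (−0.98). Their list had a median of −0.26 (adjusted p = 0.0106, camera; adjusted p = 0.36 with an estimated correlation) and −0.14 in Cy5 alone. The count adjusted over the list alone was 10 lower. Of 32 ionocyte genes, 2 were lower, atp1a1a.2 and the carbonic anhydrase gene ca2 (−0.73, SE 0.11), with a median of −0.32 (adjusted p = 0.00174, camera; adjusted p = 0.579 with an estimated correlation). Members lower when adjusted over the list alone numbered 4. Of 47 hypoxia and glycolysis genes, 3 were lower: tpi1b (−1.25, SE 0.208), gapdh (−0.85) and pfkfb4b (−0.62; 1 of 2 other probes opposing). With p adjusted over the list alone, 9 were lower. Their list had a median of −0.30 (adjusted p = 0.00296, camera; adjusted p = 0.555 with an estimated correlation). In Cy5 alone ionocytes stood at 0.04 and hypoxia at 0.135, the opposite direction.

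Nervous system genes were higher in G3 than in G4 as a list (median 0.18, adjusted p = 4.06e-06, camera; adjusted p = 0.36 with an estimated correlation), with −0.03 in Cy5 alone. gad2 (0.69, adjusted p = 0.0509) and dpysl3 (0.46, adjusted p = 0.0667) did not pass. The named genes higher in G3 were led by rab42a (1.12, SE 0.216), herc56.3 (0.92) and septin5b (0.89). ralgps2, pi4kab, gnptab, cxcl19, pawr, fzd3a, herc56.4 and pcdh1g32 lay between 0.72 and 0.86. For gnptab and pawr, 1 of 2 other probes opposed, and cxcl19, a chemokine gene, was dim in the G4 Cy3 pool. In Cy5 alone herc56.3 stood at −0.84, herc56.4 at −0.79, gnptab at −0.61, fzd3a at −0.23 and ralgps2 at −0.10, the opposite direction. Other named genes lower in G3 were and2 (−2.16, SE 0.384), and3 (−2.12, SE 0.436), ckba (−2.06, SE 0.379), tpm1, a tropomyosin (3.99-fold, SE 0.358 on the log2 scale), myoz2a (−1.91, SE 0.29) and fosab (−1.89, SE 0.243). In Cy5 alone and2 stood at 0.54, and3 at 0.37, ckba at 0.62, tpm1 at 0.77 and myoz2a at 0.38, the opposite direction, and fosab at −0.56 (adjusted p = 0.453), no longer called.

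The other lists lower in G3 were skin (median −0.45, adjusted p = 0.000138), melanophores (−0.40, 0.000227), erythrocytes (−0.34, 0.000295), the heart (−0.48, 0.000967), oxidative stress (−0.24, 0.00174), extracellular matrix (−0.27, 0.00551), xenobiotic metabolism (−0.21, 0.028) and liver (−0.33, 0.0347). Cell cycle (0.05, adjusted p = 0.0105) and ribosomal protein genes (0.04, adjusted p = 0.028) were higher. Over all probes, 3 skin, 1 erythrocyte, 1 heart, 1 oxidative stress, 5 matrix and 2 xenobiotic genes were lower. Numbers lower when adjusted over the list alone were 7 for skin, 8 for melanophores, 1 for erythrocytes, 5 for the heart, 4 for oxidative stress, 17 for matrix (with 2 higher) and 5 for xenobiotic metabolism. With an estimated correlation the lists' adjusted p lay between 0.203 and 0.824. With median centring in place of loess the ribosomal list stood at −0.30, the opposite direction. Of these 10 lists, 9 turned direction in Cy5 alone, with medians from −0.11 for the cell cycle to 0.23 for the heart, though for melanophores only the test turned (median −0.07). Without 1 array the liver call was lost in 3 fits (adjusted p = 0.143 to 0.746), G4 array 1 having a median ratio of 1.25 against 0.165 and 0.22 on arrays 2 and 3. The xenobiotic call was lost in 3 (adjusted p = 0.0585 to 0.389). Likewise the cell cycle call was lost in 3 (adjusted p = 0.0585 to 0.281, camera) and the ribosomal call in 2 (adjusted p = 0.0817 to 0.199, camera).

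Several changes were not shown to differ between the dendrimers. The intervals are those of the ratios and leave out the spread between pools. Against the control arm, s100t alone of the genes in this paragraph passed in G3. The difference of G3 from G4 was 0.39 for mmp9 (95% interval −0.86 to 1.64), −0.45 for irg1l (−1.43 to 0.54) and 0.01 for ptgs2b (−0.42 to 0.45). It was −0.02 for npvf (−0.31 to 0.28), −0.03 for pcna (−0.32 to 0.26) and −0.04 for sagb (−0.30 to 0.21). For s100t it was −0.66 (95% interval −0.91 to −0.40, SE 0.113, adjusted p = 0.0261), a lower level in G3. In Cy5 alone, G3 and G4 stood at 3.31 and 1.96 for mmp9, 2.74 and 2.18 for irg1l, and 1.75 and 1.89 for ptgs2b. They stood at −0.96 and −0.54 for npvf, 0.48 and 0.38 for pcna, and −0.47 and −0.98 for sagb. The acute phase and inflammation list differed by a median of 0.01 and a mean of −0.01 (adjusted p = 0.46), camera pointing up and fry down, while in Cy5 alone G3 stood 0.33 above G4. Within it, tnfb differed by 1.12 (0.44 to 1.80; adjusted p = 0.0921), and ccl20a.3, a chemokine gene chosen after values were seen, by 0.84 (0.43 to 1.26; adjusted p = 0.0513). Both were higher adjusted over the list alone, where fosab and ccl34b.1 were lower, but not over all probes. The remaining 11 lists, among them neutrophil and macrophage markers (−0.165, adjusted p = 0.187) and the DNA repair and apoptosis list (−0.105, adjusted p = 0.439), had adjusted p between 0.127 and 0.974. Tested in either direction, fry called 21 of the 29 lists between G3 and G4, among them 7 of these 12 lists. They were DNA repair and apoptosis (adjusted p = 0.00885), endothelium (adjusted p = 0.00905), early embryo (adjusted p = 0.0287), hatching gland (adjusted p = 0.029), inflammation and circadian clock (adjusted p = 0.0355 each) and cholesterol synthesis (adjusted p = 0.0374).

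**Figure D2:**
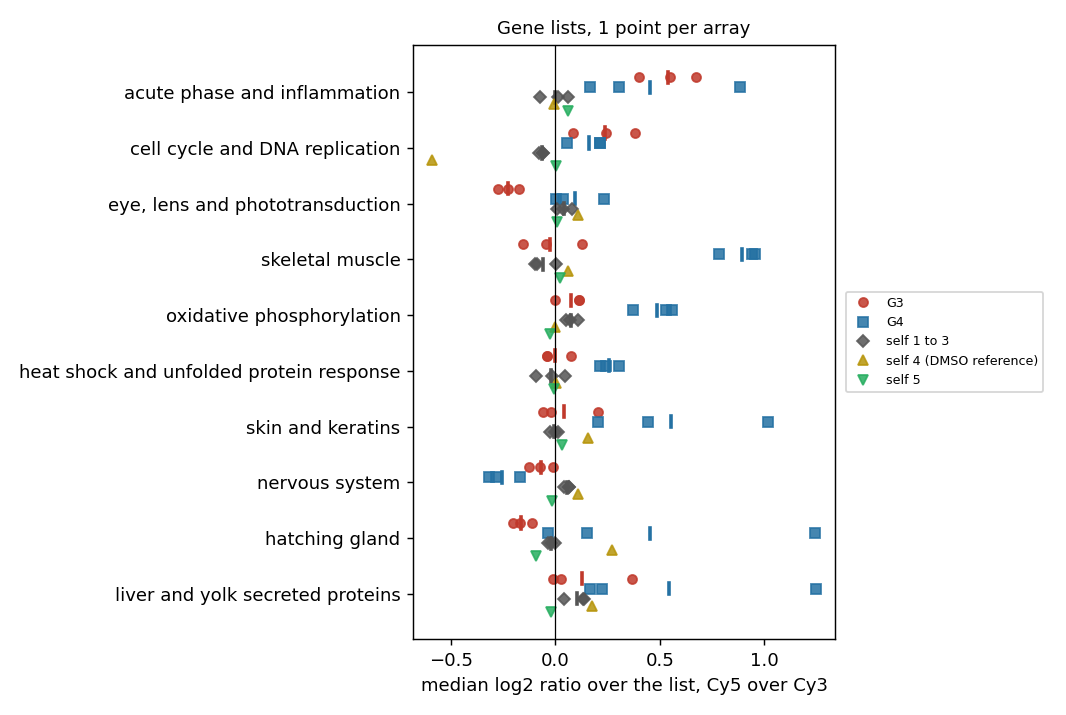
Each point is the median log2 ratio of Cy5 over Cy3 of the measured genes of a list on 1 array, for 10 lists, and ticks mark the mean of 3 arrays. The muscle list lies between 0.785 and 0.957 on the G4 arrays and between −0.15 and 0.13 on the G3 arrays.

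Across 11769 genes, the G3 and G4 changes against the shared control arm correlated at r = 0.519 (rho = 0.542), while 100 simulations without any effect gave a mean r of 0.602 from the shared control arm alone. The simulations gave all arrays and control units of a gene the same spread, so the group sizes fix the simulated r. Whether the observed r lies above or below what chance gives is therefore not decided. Genes are not independent replicates. The covariance was 0.0503 against 0.0218 simulated, 69.3% of genes had the same sign against 70.5% simulated, and with separate controls r was 0.333. 1 gene, s100t, fell in both.

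The count of 829 was 47 without G3 array 3, 516 without G4 array 1, 98 without G4 array 3, 515 without self-to-self array 1 and 252 without array 2 or with arrays 1 to 3 as 1 unit. With median centring it held 22 higher and 1048 lower, and it was 155 with slides as blocks, where 30 of 41 named genes were no longer called, and 64 in Cy5 alone, where 16 of the 41 lost their call and 25 turned direction.

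**Figure D3:**
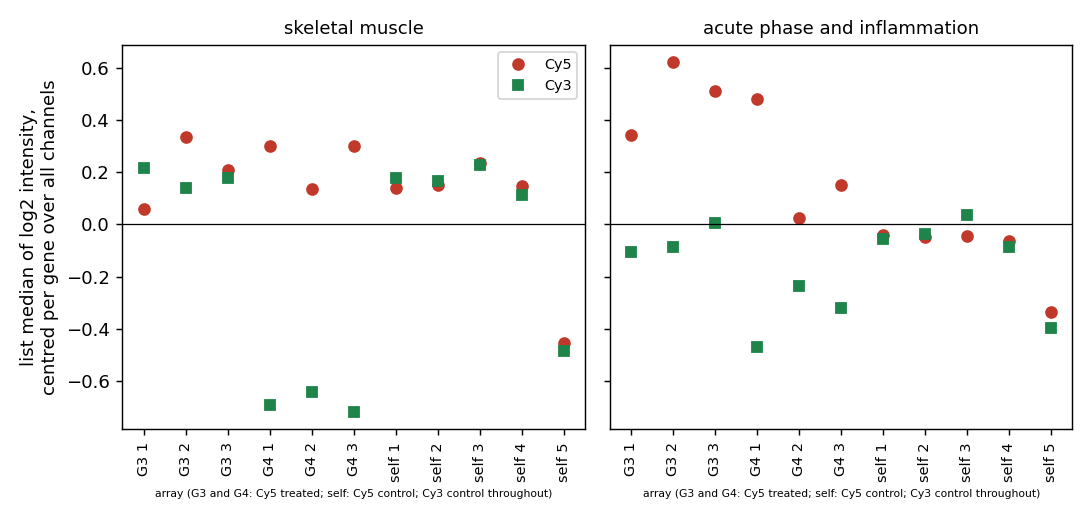
Points are the median log2 levels of the skeletal muscle and the inflammation lists in Cy5 and in Cy3 on each array, centred per gene over all channels. The muscle level in Cy3 lies between −0.72 and −0.64 on the G4 arrays and between 0.14 and 0.23 on the G3 and self-to-self arrays 1 to 3.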

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

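Of the tests in this part, the 2 on other splits of the arrays were written before the results were seen, and those on channels, pools, slides and leukocyte markers were chosen after.

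G3 and G4 differed in 829 probes and 17 gene lists by a test of the difference itself. Of the 10 splits of the 6 treated arrays into 3 and 3, 1 called as many probes as the real split, which was the real split itself, and the highest count of the others was 0 (limma). For lists, 2 of 10 splits called as many as the real 17, and the highest of the others was 17, for G3 arrays 1 and 2 with G4 array 2. With an estimated correlation camera called 0 of the 17 lists (smallest adjusted p = 0.203), and fry called 6 lists. With 10 splits the share cannot fall under 0.05.

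Among the genes called between G3 and G4, 142 had ratios of opposite sign in all arrays of the dendrimers, and 129 of these were lower in G3. The widest differences were those of hspb9 (−3.70), atp1a1a.2 (−2.29), myoz2a (−1.91), kcnj1a.2 (−1.85) and tnnt3a (−1.65), each with all G3 ratios below 0 and all G4 ratios above 0. In Cy5 alone hspb9 was −1.31, atp1a1a.2 −0.525 and kcnj1a.2 −0.465, not called, while myoz2a was 0.381 and tnnt3a 0.125, the opposite direction.

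Skeletal muscle genes were higher on the G4 arrays than in the control arm by a median of 0.94. A difference between slides is argued against, since the lowest within-slide difference was 0.743, which is over 0.5 of that median. A low level of these transcripts in the Cy3 pool of the G4 arrays could account for the pattern: in Cy5 alone the change was 0.061 (SD between arrays 0.0941). An effect of G4 on embryos whose own level was as low as that of their pool cannot be told apart. Self-to-self array 5 (Cy5 level −0.457) holds the same pool and not a second one. Array 2, also labelled with this pool, had a Cy5 level of 0.151, but its label is in doubt. With such an effect of G4 the ratios would hold a response, and with a low pool alone an unusual pool.

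Self-to-self array 2, labelled with the G4 pool, differed from the Cy3 of the G4 arrays. A wrong label on this array may explain it, since the lowest correlation of its Cy3 with that of a G3 array was 0.979. Across the same probes its correlation with the G4 array on its own slide was 0.949, below all of those with G3 arrays on other slides, which argues against a difference between slides. Self-to-self array 5 had correlations of 0.986 to 0.997 with the Cy3 of the G4 arrays. No biological explanation was tested, and the control arm of the report rests on array 2 as labelled: were the label wrong, arrays 1 to 3 would be repeats of 1 pool, and counted as 1 unit they leave 0 probes called in G3 and 0 in G4.

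Inflammation genes were higher in G3 (0.53) and in G4 (0.49) than in the control arm. For G3, the change in Cy5 alone was 0.473 (SD between arrays 0.14), but self-to-self arrays 1 and 3 of the control arm hold that same pool. The list's Cy3 level, centred per gene, was −0.107 to 0.004 on the G3 arrays and −0.469 to −0.238 on the G4 arrays. In the DMSO pool, measured on array 4 only, it was −0.086. These levels argue against a G3 pool that was low for this list among the pools measured. Another pool of unexposed embryos of the G3 arrays was not measured. For G4 the change in Cy5 alone was 0.22 (SD 0.236). There a low pool cannot be told apart from a response, the spread between arrays being too wide. A first criterion without this spread had counted 0.22 for the pool. More neutrophils and macrophages as the source of the G3 change cannot be told apart from a change within cells, since 18 markers outside the list, 13 of them above 0, had a median of 0.206 and its 95% bootstrap interval over genes (−0.02 to 0.39) holds 0.266, which is 0.5 of the list's median; a first criterion had not asked the interval to lie under 0.266. A response of the embryos to G3 stays open as a hypothesis, found and tested on the same arrays.

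On self-to-self array 4, which compared the G3 pool with a DMSO pool and was used in no comparison, 3.68% of probes had a log2 ratio of size 1 or more, against 0.832% to 0.931% on arrays 1 to 3. Its median ratio was −0.59 for cell cycle genes and 0.27 for the hatching gland list, outside the range of arrays 1 to 3.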

How the results depend on the processing

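Chosen after the data were seen were array 5 alone as control, arrays 1 and 2 averaged, arrays 1 to 3 as 1 unit, Cy5 alone and the doubted arrays left out. The cause of the changes below was not tested, except that settings with fewer arrays have less data; the signal over background limits the dimmest probes. With the deposited values and a trended robust prior, the total counts, lists and correlation of every comparison stayed within 1.5 times or their spread. With that prior, probes lower in G4 than in the control arm went from 184 to 113. Those higher in G3 than in G4 went from 145 to 91.

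The G3 count of 1 probe became 2 without background correction, 4 with scaling between arrays, 145 against 0, 29 with self-to-self arrays unaveraged, 43 with arrays 4 and 5 added, 10 with only the groups compared, 75 with array weights, 2 with the replicate block and 15 in Cy5 alone. It became 0 with the scanner ratios (1895 at unadjusted p under 0.05, limma), the slide block (2516), array 5 alone (691), arrays 1 and 2 averaged (1215), arrays 1 to 3 as 1 unit (415), and without G3 array 2 and self array 2 (294). Leaving out 1 array gave 0 to 53: 53 without G4 array 1, and 0 without G3 array 1 (4100), 2 (1260) or 3 (1933), G4 array 3 (1531) or self array 2 (411). The G3 lists, 8, were 5 to 10 with 1 array left out (5 without G3 array 1), 11 without G3 array 2 and self array 2, 0 with the estimated correlation and 0 with fry.

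The G4 count of 848 became 1446 with median centring (1422 higher, 24 lower), 1335 with scaling, 6336 against 0, 3132 unaveraged, 3026 with arrays 4 and 5, 9279 with array weights, 1635 with the replicate block, 292 with the slide block, 374 with the fold threshold, 268 with arrays 1 and 2 averaged and 28 in Cy5 alone (13 higher, 15 lower). It was 0 with array 5 alone (3578 unadjusted), with arrays 1 to 3 as 1 unit (3744) and without G4 array 1 and self array 2 (2787). Leaving out 1 array gave 0 to 2545: 1819 without G3 array 2, 152 without G3 array 3, 512, 1888 and 1 without G4 arrays 1, 2 and 3, and 331, 0 (3631 unadjusted) and 2545 without self arrays 1, 2 and 3. The G4 lists, 17, were 0 with the estimated correlation, 6 with fry, 7 in Cy5 alone and 16 to 20 with 1 array left out.

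Between G3 and G4, 829 (145 higher, 684 lower) became 252 with only the groups compared, 3792 with array weights (1584 and 2208), 155 with the slide block, 302 with the fold threshold, 64 in Cy5 alone, 252 with arrays 1 to 3 as 1 unit and 1377 without G3 array 2 and G4 array 1; the replicate block gave 723 and median centring 1070 (22 and 1048). Leaving out 1 array gave 47 to 1045: 47 without G3 array 3, 516 and 98 without G4 arrays 1 and 3, and 515 and 252 without self arrays 1 and 2. The lists, 17, were 0 with the estimated correlation, 6 with fry and 14 to 20 with 1 array left out, and 3 higher and 14 lower became 13 and 2 in Cy5 alone. The correlation of G3 with G4 was 0.333 with separate controls and 0.40 to 0.59 with 1 array left out.

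With 1 array left out, named genes stayed on their side of the threshold in 137 of 144 values for G3, 192 of 342 for G4 and 223 of 369 between G3 and G4, and called lists in 68 of 72, 151 of 153 and 142 of 153. No gene and no list test turned direction. The slide block ended the calls of 23 of 38 named genes in G4 and of 30 of 41 between G3 and G4, and arrays 1 to 3 as 1 unit those of 38 and 24. Only the groups compared ended 12 and 24, the fold threshold 13 and 21, and the scanner ratios 12 and 14. Median centring ended 10 and 11, the mean of a gene's probes 7 and 9, and arrays 1 and 2 averaged 22 in G4. Cy5 alone ended 28 and turned 9 in G4, and ended 16 and turned 25 between G3 and G4. Array 5 alone, and G4 array 1 and self array 2 left out, each ended all 38 in G4.

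Replicate numbers did not pair the arrays: ratios after removing group means correlated across probes at 0.001, −0.405 and 0.229 for G3 and G4 of the same number, so the replicate block is given as an alternative. G3 and G4 arrays that share a slide correlated at 0.338 (slide 2) and 0.467 (slide 3).

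Directions turned as follows. With median centring, the ribosomal list between G3 and G4 was −0.297. Against 0, ribosomal proteins were 0.167 in G3 and 0.133 in G4 and rpl24 0.206. Without G3 array 2 and G4 array 1, the liver list was −0.031. In Cy5 alone the G4 lists that turned were oxidative phosphorylation −0.025, ribosomal 0.023, neutrophil −0.028, skin −0.174, xenobiotic −0.037, heart −0.168, matrix −0.061 and lipid −0.024; the genes were ckba −0.29, and2 −0.279, jac7 −0.017, tnni2a.4 −0.29, pvalb4 −0.531, pcdh2ac 0.008, ralgps2 0.066, nfia 0.42 and fam168b 0.058. Between G3 and G4 in Cy5 alone, the lists were oxidative phosphorylation 0.088, nervous system −0.029, eye 0.068, skin 0.124, melanophores −0.068, heart 0.229, oxidative stress 0.065, ionocytes 0.043, hypoxia 0.135, matrix 0.109, cell cycle −0.112, ribosomal −0.074, xenobiotic 0.14 and liver 0.22. The genes were herc56.3 −0.842, ralgps2 −0.1, gnptab −0.61, fzd3a −0.226, herc56.4 −0.79, tnni2a.4 0.054, and2 0.536, and3 0.37, ckba 0.616, tpm1 0.773, pvalb4 0.66, myoz2a 0.381, actc1a 0.132, tnnt3a 0.125, ndufa7 0.372, ndufs7 0.314, slc25a4 0.126, uqcrc1 0.031, gad2 −0.047, dpysl3 −0.338, crygm2d13 0.341, crygmx 0.136, bfsp2 0.001, cryaa 0.013 and gapdh 0.169. Where a list's median kept its sign, its test turned. The cell cycle median between G3 and G4 fell as low as −0.131 in another alternative, where its test kept its direction.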

Other observations

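The genes in this part were chosen after their values were seen. In G3, the parathyroid hormone gene pth1a had a log2 change of −1.22 (SE 0.141, adjusted p = 0.0919, limma), the transglutaminase gene tgm1l4 −1.09 (SE 0.129), the annexin gene anxa5a −1.09 (SE 0.133) and the sodium pump subunit atp1b1b −1.02 (SE 0.15), none of which passed. Between G3 and G4, pth1a differed by −1.16 (adjusted p = 0.00782), tgm1l4 by −0.97 (adjusted p = 0.00944) and anxa5a by −0.93 (adjusted p = 0.00965), with all 3 G3 ratios below all 3 G4 ratios. In Cy5 alone pth1a stood at −1.22 in G3 and −0.37 in G4, while anxa5a stood at −1.15 in G3 and −1.09 in G4, with −0.92 in the Cy3 pool of the G4 arrays, and tgm1l4 at −1.15 and −0.58, with −0.45 in that pool. stard14 rose by 1.71 in G4 (SE 0.217, adjusted p = 0.018) and stood at 1.52 in G3 (SE 0.217, adjusted p = 0.163). Their difference was −0.19 (95% interval −0.63 to 0.25), and in Cy5 alone the values were 1.38 and 1.59. cyp1a, a xenobiotic-metabolizing enzyme, stood at 1.15 in G4 (adjusted p = 0.0598) and differed by −1.27 between G3 and G4 (adjusted p = 0.0346), with −0.02 and −0.03 in Cy5 alone in G3 and G4 and −1.18 in the Cy3 pool of the G4 arrays.

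The hatching enzyme gene he1.1 had ratios of −0.76, −2.31 and −3.21 on G3 arrays 1, 2 and 3. On the G4 arrays they were 4.14, 0.84 and 0.88, and on self-to-self array 4 the ratio was 1.83. hsp70.3 had a ratio of 4.14 on G4 array 3, against 0.84 and 0.86 on G4 arrays 1 and 2. G4 array 1 stood apart in secreted liver proteins, with a list median of 1.25 against 0.165 and 0.22 on G4 arrays 2 and 3. Its complement list was at 1.41 against 0.25 and 0.41, and its hatching gland list at 1.24 against −0.03 and 0.15. On this array 6.18% of probes had a log2 ratio of size 1 or more, against 1.12% and 2.02% on the other G4 arrays and 0.0311% on self-to-self array 5. The ratios of self-to-self arrays 1 and 2, labelled with different pools, correlated at 0.913 across probes, and those of arrays 1 and 3, labelled with the same pool, at 0.503.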
